A study of Mus musculus with 8 samples.

How the data were processed

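Gene expression was measured by RNA sequencing of polyadenylated RNA in primary cortical neurons of E16.5 mouse embryos, kept in culture for 12 days. The 8 libraries were 4 of wild-type neurons and 4 of neurons in which the histone gene H2bc21, which encodes the H2B variant H2BE, had been knocked out by an mCherry knock-in, per the labels. The labels call the libraries of each genotype biological replicates. Groups were taken from the genotype in the labels.

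The values come from 1 table of the authors' own comparison of the genotypes, with 26229 genes. Reads were mapped to the mouse build mm10 and compared with DESeq2, and DESeq is also named, per the submitters' processing notes, which give no versions. The aligner, the counting tool, the use of strand in counting and the gene annotation are not given in the sources used here. For each gene the deposited signal is a mean normalized count over all libraries, that is, counts divided by size factors and averaged, per the file headers. The deposited log2 fold change and its standard error are on the log2 scale, per the file headers. The deposited score is a Wald statistic. It was checked to equal the log2 fold change divided by its standard error, with a largest gap of 2.86e-07. The deposited p-value was checked to be the two-sided normal p of that score, and the deposited adjusted p-value to be the Benjamini-Hochberg adjustment of it over the tested genes. Their largest relative gaps were 0.477% and 0.757%, which is rounding in the table.

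Of the 26229 genes, 18085 had an adjusted p and were counted as tested. Another 8135 had a p but no adjusted p, and all of these had a mean normalized count of at most 2.99, below that of every tested gene. The remaining 9 genes had neither and were not tested. A missing adjusted p was kept as missing. No values per library were used, so nothing here gives the spread of single libraries, their depth or a refit of the model, and no count model was run here. The mean normalized counts summed to 3.96e+07, which is the average library total after scaling.

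The header names no direction for the fold change. The rule fixed before the data were examined was to take the sign from the targeted gene, which the knockout should remove. H2bc21 had a positive deposited value, so positive deposited values were read as higher in wild type and every sign was turned to knockout over wild type. This is an inference. The labels do not say which part of the gene the mCherry cassette replaced, and with most of the transcript being 3' untranslated region, reads from remaining parts could count towards it. If the sign were the other way round, every "higher" and "lower" below would swap.

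Genes were matched by Ensembl identifier to the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and 26039 rows matched. Symbols are those of the deposited table. For 5845 rows without a symbol, the annotation's name was used for 5655. Exon length is the union of annotated exons, and GC content is that of the longest annotated transcript.

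A gene was called at a deposited adjusted p under 0.05. The share of calls lower in the knockout was given with an exact binomial 95% interval, as a description of the table, since genes are not independent. The 35 gene lists, each with at least 5 tested members, were fixed before the data were examined. Each list was tested two-sided against all other tested genes with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistic, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 35 lists. A correlation could not be estimated without values per library, so 0.05 and 0.1 were also preset. Members past the threshold were counted with the deposited adjusted p and again adjusted over the list alone, and enrichment of calls in each direction was tested with two-sided Fisher exact tests. Expression level and length of called genes were compared with permutation tests of the difference of medians (100000 resamples) across genes, which are not replicates. The design fixed beforehand allowed for counts or a comparison table, and the plan for a comparison table was followed. Pseudogenes were aligned to their parent transcripts with Biopython 1.88. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.

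Genes were named by a rule fixed beforehand. It takes the targeted gene, the 10 largest rises and 10 largest falls among called genes with a mean normalized count of at least 50, the 5 smallest adjusted p in each direction, and in each list up to 4 called members with the smallest adjusted p or, with none called, up to 2 members of highest mean count. Symbols that are Gm with digits, end in Rik or are bare identifiers were skipped, 1 among the rises, 4 among the falls and 2 among the smallest adjusted p of the lower genes. Sv2a, the parent genes of the pseudogenes and genes named only in the closing section were chosen after their values were seen. Some genes that the rule names are not reported here.

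The procedures were tested on simulated data. Statistics were drawn for the 18085 tested genes with their deposited standard errors, with 200 genes changed per round in 50 rounds. At a mean normalized count of at least 100, 85.4% of changes of log2 1 and 41.6% of log2 0.5 were recovered, against 56.4% and 26.7% over all genes, and 4.99% of the calls were false. The list test called a shifted list of 40 genes in 100 of 100 rounds and 1 of 1900 unshifted lists. Independent genes and the normal null were built into the simulation, so the false shares follow from its construction and say nothing of the wider real statistic or of correlation between genes. The recovered shares hold for 200 changed genes per round. In the real data 3948 genes were called, which moves the cutoff on p, so these shares do not describe it.

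Alternatives were other thresholds of adjusted p (0.01 and 0.1), minimum fold changes, filters on the mean count, adjustment without independent filtering, a t distribution with 6 degrees of freedom, a test of an absolute log2 fold change over 0.25, an empirical null, named features only, and centred fold changes. For the lists they were other correlations, rankings and backgrounds and 10000 random lists matched on mean count. Chosen after seeing the data were a restriction to protein-coding genes and the removal of a trend of the statistic with exon length and GC content by lowess with a span of 0.3.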

Results

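RNA of cultured mouse cortical neurons was compared between wild type and a knockout of H2bc21, the gene of the histone variant H2BE, with 4 biological replicates per genotype. H2B is a core histone of the nucleosome. Neurons were taken at E16.5 and grown for 12 days. The question the design addresses is which transcripts differ when neurons lack H2BE. All fold changes, standard errors (SE) and adjusted p values come from the authors' deposited table and are written as knockout over wild type, a direction read from the targeted gene. If the direction were the other way round, every rise and fall would swap. The SE carries the spread between the 4 and 4 replicates. Depth per library was not analysed here. The mean normalized counts, averaged over all libraries, summed to 3.96e+07. Precision followed the count: the median SE of log2 fold changes was 0.664 for the 6548 genes under a mean count of 100, 0.198 for the 4729 genes from 100 to 1000 and 0.127 for the 6808 genes above.

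The targeted gene H2bc21 (ENSMUSG00000068854, named Hist2h2be in the annotation) had the smallest adjusted p of all tested genes. The authors' deposited table gave a log2 fold change of -3.45 (SE 0.19, 95% interval -3.83 to -3.08, adjusted p = 4.49e-68) at a mean normalized count of 1109. It lies on the plus strand of chromosome 3 from 96221119 to 96223738 in GRCm38, as a single exon. The coding part runs from 96221166 to 96221543, and 2195 of its 2620 bases are 3' untranslated region including the stop codon. With the direction set by this gene, the knockout level was 9.12% of wild type. The labels do not say which part was replaced, and H2B coding sequences are alike between genes, so the remaining level is uncertain. None of the 6 other H2B genes tested passed the threshold. H2bc27 had a log2 fold change of 0.20 (SE 0.18) and H2bc4 of -0.66 (SE 0.29, adjusted p = 0.0835). The divergent neighbour H2ac20, a histone H2A gene, fell to a log2 fold change of -2.47 (SE 0.76, adjusted p = 0.00907) at a mean count of 10.7. Of the 16 tested genes within 0.2 Mb, the other one past the threshold, named after its value was seen, was Sv2a, a synaptic vesicle glycoprotein gene, at -0.30 (SE 0.09, adjusted p = 0.00893). Within 5 Mb either side of the target, 8 of 141 other tested genes rose and 17 fell, or 17.7%, against 21.8% of all tested genes. By cameraPR the region did not stand apart (adjusted p = 0.702). Its smallest adjusted p values belonged to Zfp697 (1.20), Cgn (1.40) and Ptgfrn (0.65), which rose, and Ecm1 (-1.34), which fell. Adjusted over the list alone, 7 rose and 16 fell.

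**Figure D1:**
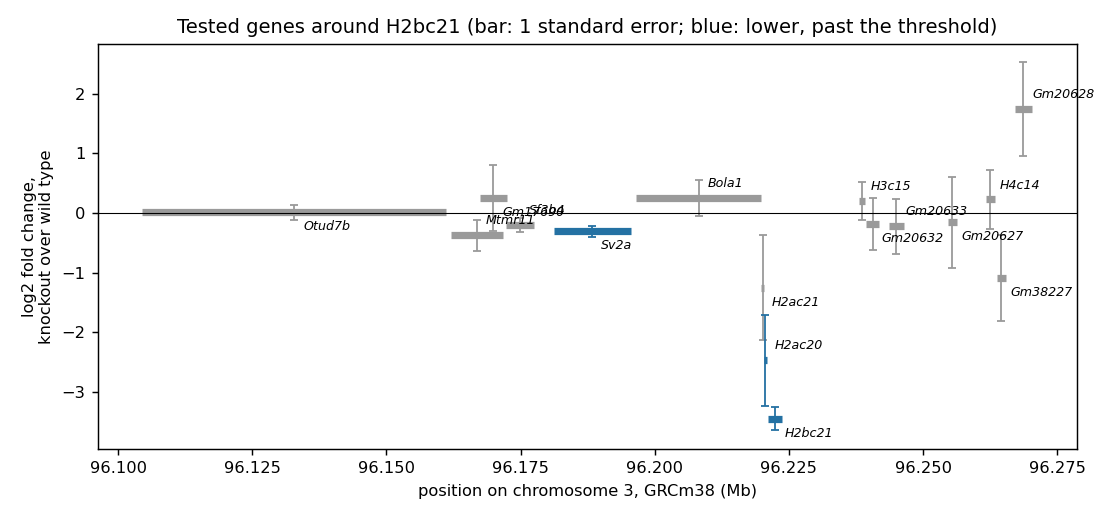
Log2 fold change, knockout over wild type, of the 16 tested genes within 0.2 Mb of H2bc21 against their position on chromosome 3 in Mb (GRCm38). Thick bars span each gene and thin bars are 1 SE from the authors' deposited table. H2bc21 lies at -3.45, with Sv2a and H2ac20 the other genes past the threshold (blue).

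Transcript levels differed widely between the genotypes. Of 18085 tested genes, 3948 (21.8%) passed an adjusted p of 0.05 in the authors' deposited table, 1981 higher and 1967 lower in the knockout, with median log2 fold changes of 0.68 and -0.66. The share lower was 49.8% (exact binomial 95% interval 48.3 to 51.4). A change of at least log2 1 was reached by 623 of the higher and 607 of the lower genes. Among named genes with a mean normalized count of at least 50, the largest rises were those of Dmrt2, a DM-domain transcription factor gene, at 23.6-fold, and Aldh1a3, a retinaldehyde dehydrogenase gene, at 16.8-fold. They were followed by Prokr1 (16.2-fold), Cdhr1 (14.8-fold), Abca8a (11.9-fold), Cav1 (11.4-fold), Rgs9bp (10.7-fold), Dsc3 (9.05-fold), Ccbe1 (8.92-fold) and Prss35 (8.90-fold). Their log2 SEs ran from 0.37 for Prss35 to 0.98 for Dmrt2. The largest falls by the same rule were those of Rpl15-ps2 (log2 fold change -9.60, SE 1.56) and BC002163 (-5.59, SE 0.40), both annotated as processed pseudogenes and near-identical to Rpl15 and Ndufs5, so that their read counts are uncertain. Tnmd (-4.67), Ptgs2 (-4.59), Ppp1r1c (-4.57), Spink2 (-3.97), Emp1 (-3.91), Hpse (-3.84), Lce1g (-3.66, SE 1.29) and Crisp1 (-3.46) followed. Among abundant genes with small error, Stat2, a transcription factor gene of interferon signalling, rose 2.80-fold (adjusted p = 1.46e-24). Camkv, a kinase-like synaptic protein gene, rose to a log2 fold change of 1.21, Vcan, the gene of the matrix proteoglycan versican, 3.80-fold, Akap7 2.97-fold and Nol4l 1.79-fold. After H2bc21 and BC002163, the smallest adjusted p values of lower genes were those of Trmt2b (-1.48), Wdfy1 (-1.78) and Kcnip1 (-1.48), the gene of an auxiliary subunit of A-type potassium channels. The count depended on the null distribution: with an empirical null, whose scale was 1.96 times that of the normal, 74 genes passed and 31.1% of them were lower, and with a t distribution of 6 degrees of freedom only H2bc21 passed.

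**Figure D2:**
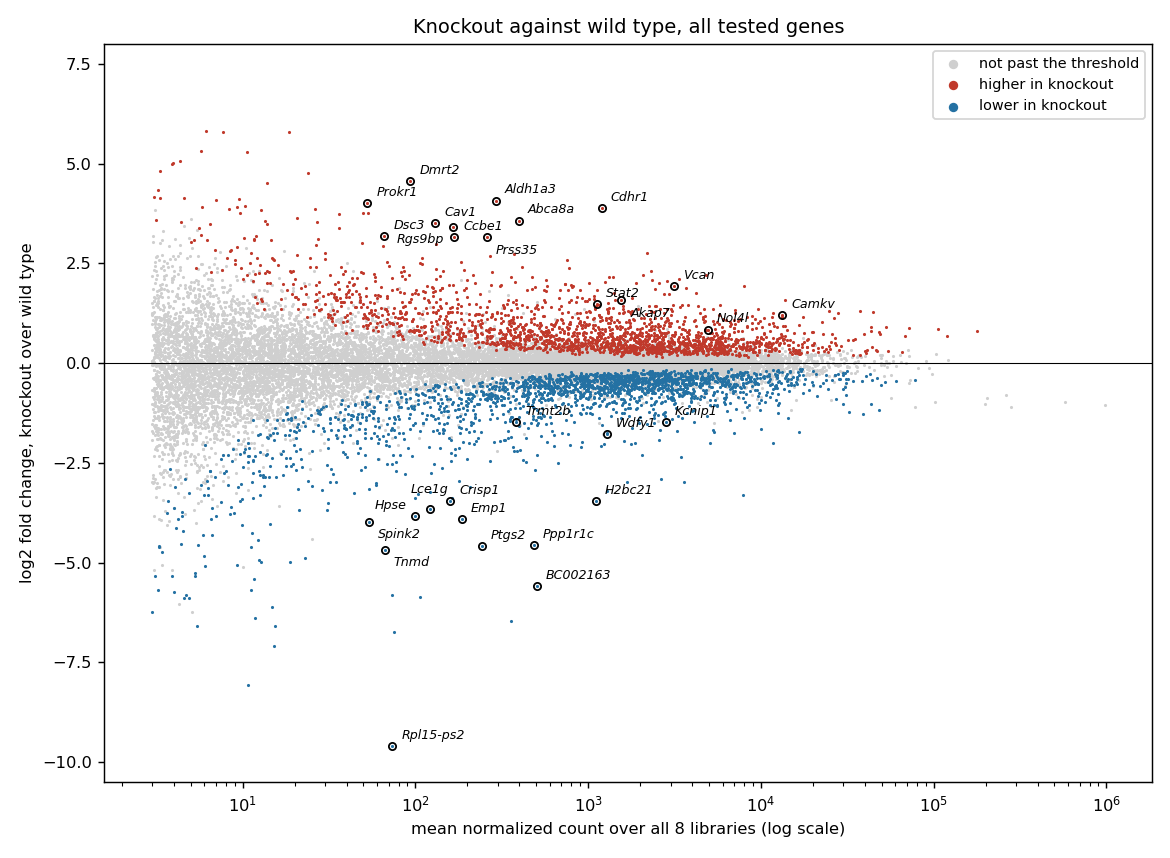
Log2 fold change, knockout over wild type, against the mean normalized count over all 8 libraries (log axis) for the 18085 tested genes of the authors' deposited table. Red points are the 1981 genes higher and blue points the 1967 genes lower in the knockout. Open circles mark the named genes with the largest changes and the smallest adjusted p.

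Genes of energy metabolism fell and genes of sterol synthesis rose. Of 99 nuclear-encoded oxidative phosphorylation genes, 57 fell and none rose, with a median log2 fold change of -0.57 (cameraPR adjusted p = 3.08e-17). Adjusted over the list alone, 71 fell and 2 rose. In the authors' deposited table Sdha, a succinate dehydrogenase subunit gene, was at -0.49 (SE 0.06), Cox6a2 at -1.77 (SE 0.29), Ndufa9 of complex I at -0.52 (SE 0.09) and Atp5d of the ATP synthase at -0.72 (SE 0.14). The 27 transcripts encoded by the mitochondrial genome gave 1 call, the proline transfer RNA mt-Tp at -2.01 (SE 0.55), and 1 adjusted over the list alone. Of them 20 lay below 0, with a median of -0.76. The list did not pass with the Wald statistic (adjusted p = 0.105) but did by log2 fold change (1.45e-05) and by ranks (0.0472). Without the trend with exon length and GC content, which left 13 members, it pointed up (adjusted p = 0.838), and it gave 0.215 against matched lists. Of 25 genes of cholesterol synthesis and uptake, 22 rose and none fell, with all 25 above 0 and a median of 1.04 (adjusted p = 7.78e-22, 23 higher adjusted over the list alone). Hmgcs1 rose to 1.28 (SE 0.18), Sqle, the gene of squalene epoxidase, to 1.17 (SE 0.16) and Acat2 to 1.37 (SE 0.19). Both calls held under every alternative, including removal of the trend with exon length (adjusted p = 4.91e-11 and 3.95e-20). Cytosolic ribosomal protein genes were shifted down by little: 81 of 87 lay below 0 with a median of -0.29 (adjusted p = 0.00196), yet 2 passed as single genes, Rpl39l (-2.58) and Rpl3l (-2.38), both of low count, and 1 adjusted over the list alone. That list lost its call when the trend with exon length and GC content was removed (adjusted p = 0.143) and at a correlation of 0.05 (adjusted p = 0.119).

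Markers of immature neurons and of cortical projection neurons rose and those of GABAergic interneurons fell. Of 18 immature neuron markers, 10 rose and 1 fell, with a median log2 fold change of 0.96 (adjusted p = 4.12e-06, 12 and 1 adjusted over the list alone). Per the authors' deposited table Tbr1, a transcription factor of early-born projection neurons, rose to 1.90 (SE 0.28), Dcx, the gene of doublecortin, to 1.32 (SE 0.21), Neurod2 to 1.12 (SE 0.21) and Tubb2b to 0.88 (SE 0.16). Of 27 layer markers of projection neurons, 16 rose and 4 fell, with a median of 0.90 (adjusted p = 1.33e-08, the same counts adjusted over the list alone). Ldb2 rose to 2.76 (SE 0.36), Etv1 to 1.98 (SE 0.24), Lmo3 to 0.97 (SE 0.14) and Plxnd1 to 0.90 (SE 0.12). Both calls held under every alternative. Tbr1 belongs to both lists, so they are not fully separate. Of 28 interneuron markers, 11 fell and 1 rose, with a median of -0.76 (adjusted p = 0.00235, 13 and 1 adjusted over the list alone). Npy, the gene of neuropeptide Y, was at -2.89 (SE 0.41), Lhx6 at -1.26 (SE 0.27), Nxph1 at -1.14 (SE 0.25) and Gad1, a GABA-synthesizing enzyme gene, at -1.02 (SE 0.29). The interneuron call was lost at a preset correlation of 0.05 (adjusted p = 0.051) and of 0.1 (adjusted p = 0.186). General neuron markers gave 9 higher and 3 lower of 21, with a median of 0.14 (adjusted p = 0.0448, and 0.0541 without the trend with exon length and GC content). The adjusted p was 0.163 at a correlation of 0.05, 0.543 by log2 fold change, 0.137 by ranks, 0.0912 on genes of mean count 100 or more and 0.202 against matched lists. Adjusted over the list alone, 10 were higher and 3 lower. Stmn1 (1.14), Tubb3 (0.74) and Mapt (0.68) rose, and Nefh, the heavy neurofilament gene, fell to -1.75 (SE 0.25).

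**Figure D3:**
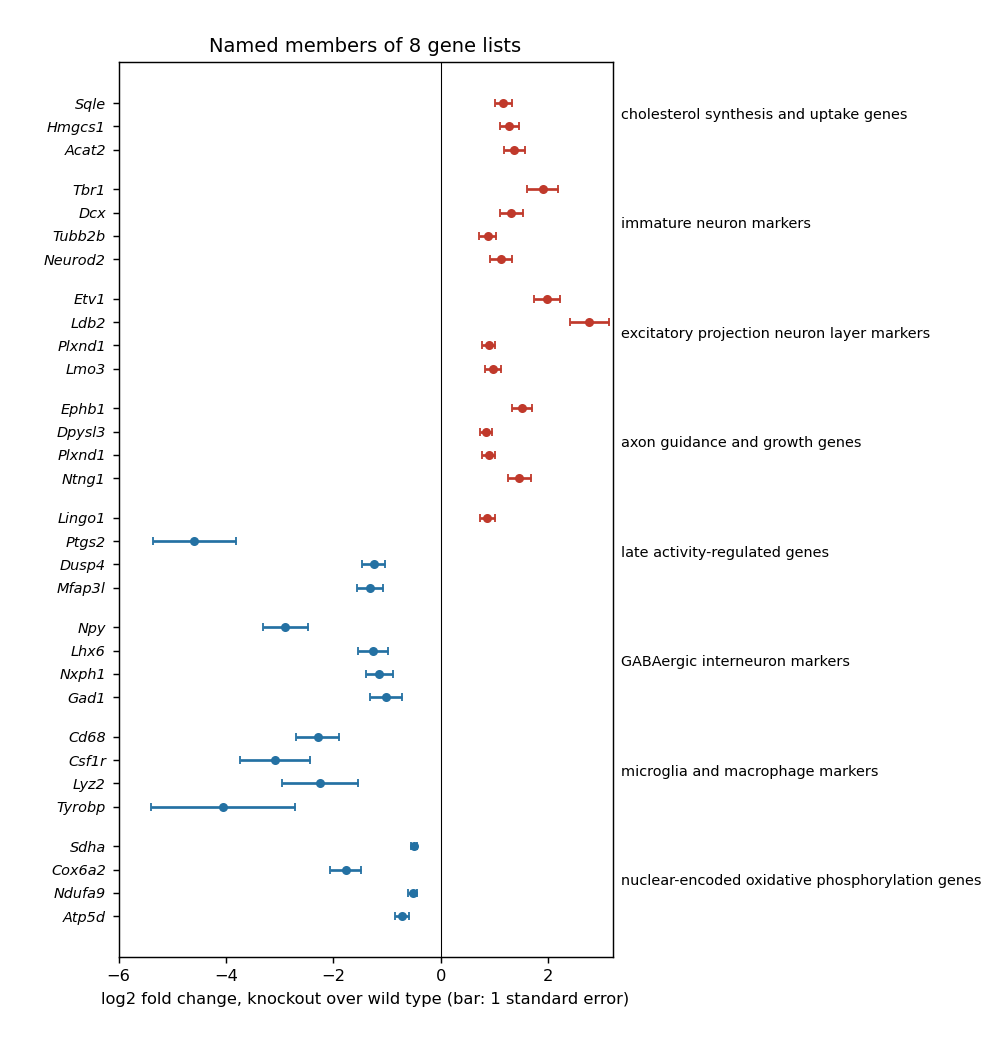
Log2 fold change, knockout over wild type, of the named members of 8 gene lists, with 1 SE on either side, from the authors' deposited table. Red points are higher and blue points lower in the knockout. Cholesterol genes such as Sqle lie near 1.17, and oxidative phosphorylation genes such as Sdha near -0.49 with small errors.

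Axon guidance and growth genes rose as a group, whereas most synaptic lists held calls in both directions. Of 57 axon guidance genes, 27 rose and 5 fell, with a median of 0.31 (adjusted p = 1.96e-06, 29 and 8 adjusted over the list alone, 0.0821 at a correlation of 0.1). By the authors' deposited table the receptor gene Ephb1 was at 1.52 (SE 0.19), Dpysl3 at 0.85 (SE 0.11) and Ntng1 at 1.46 (SE 0.21). Clustered protocadherins, cell-surface genes of neuronal identity, lay above 0 in 42 of 55 cases with a median of 0.31 (adjusted p = 0.0091, but 0.152 at a correlation of 0.05). Of them 7 rose and 1 fell, and 3 and 1 adjusted over the list alone. Pcdhb22 (0.87), Pcdhb19 (0.72) and Pcdha7 (0.50) rose and Pcdhgc3 (-0.55) fell. These genes share exons or near-identical sequence, so their counts are uncertain. Of 40 postsynaptic scaffold and signalling genes, 13 rose and 2 fell, with a median of 0.15 (adjusted p = 0.00725, but 0.13 without the trend with exon length and GC content, 0.119 at a correlation of 0.05 and 0.0913 by log2 fold change). Adjusted over the list alone, 13 rose and 3 fell. Nrgn, the gene of neurogranin, rose to 2.05 (SE 0.31), Prkcb to 1.08, Baiap2 to 0.83 and Camk2b to 0.53.

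The remaining synaptic and channel lists did not pass cameraPR. Higher calls were more frequent than among all other tested genes in the presynaptic, adhesion and channel lists (Fisher exact tests, adjusted p = 0.00344, 7.13e-04 and 3.56e-04), and lower calls in the presynaptic list (0.049). That comparison was matched neither on mean count nor on length, with which the share of calls rose, and without the trend with exon length and GC content the channel list pointed down (cameraPR adjusted p = 0.969). Presynaptic genes gave 14 higher and 12 lower of 52 (adjusted p = 0.702, 15 and 16 adjusted over the list alone). Their median was -0.07 and the test pointed down, while their mean was 0.00449. As given in the authors' deposited table, Doc2b, a calcium sensor gene of vesicle release, was at 1.36, whereas Sypl2 (-2.68), Vamp1 (-1.19) and Rab3c (-1.17) were lower. Glutamate receptor genes gave 8 higher and 7 lower of 33 (adjusted p = 0.0772, but 0.0406 against matched lists, 8 and 8 adjusted over the list alone), with Grm3 at 2.40, Grik3 at 1.94, Cacng4 at 0.62 and Shisa7 at 0.50. GABA receptor and inhibitory synapse genes gave 5 higher and 6 lower of 23, before and after adjustment over the list alone (adjusted p = 0.519). Gabra3 (0.82) and Glra2 (1.35) rose, and Gabrg3 (-1.52) and Iqsec3 (-0.93) fell. Trans-synaptic adhesion genes gave 14 higher and 7 lower of 44 (adjusted p = 0.0654, but 0.0498 by ranks and 0.0162 against matched lists, 15 and 7 adjusted over the list alone), with Lrrtm3 (1.31) and Cadm1 (0.83) higher and Flrt3 (-0.78) and Slitrk5 (-0.69) lower. Voltage-gated channel genes gave 18 higher and 11 lower of 61 (adjusted p = 0.362, 21 and 13 adjusted over the list alone). Scn1a, a sodium channel gene, fell to -1.38 (SE 0.19), whereas Cacna1e rose to 1.09 and Kcnc4 to 0.67.

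Late activity-regulated genes, which neurons induce hours after depolarization, lay lower as a list. Of 28, 15 fell, 3 rose and 10 did not pass, with a median log2 fold change of -0.87 (adjusted p = 2.44e-04, the same counts adjusted over the list alone, 0.0843 at a correlation of 0.1). The authors' deposited table placed Ptgs2, the gene of cyclooxygenase-2, at -4.59 (SE 0.78), Mfap3l at -1.31 (SE 0.24) and Dusp4 at -1.25 (SE 0.22), and Lingo1 rose to 0.87 (SE 0.14). Immediate early genes had a median of -0.60, with 5 lower and 1 higher of 27, but the list did not pass with the Wald statistic (adjusted p = 0.0566). It did by log2 fold change (adjusted p = 7.33e-04), by ranks (0.0221) and against matched lists (0.0406). Fosb was at -2.29 (SE 0.62), Atf3 at -1.29, Fosl2 at -0.77 and Gadd45g at -0.60, and the counts were the same adjusted over the list alone. Heat shock and chaperone genes fell in 7 of 21 cases and rose in none (median -0.32, adjusted p = 7.94e-04, 7 adjusted over the list alone). Hspd1, Stip1, Hspa8 and Dnajb1 lay between -0.43 and -0.32. Unfolded protein and integrated stress response genes fell in 8 of 28 cases (median -0.23, adjusted p = 0.029). Adjusted over the list alone 8 fell and 1 rose. Nupr1 (-1.74), Sdf2l1 (-1.18), Ddit3 (-0.75) and Calr (-0.67) led. The heat shock call was lost at a correlation of 0.1 (adjusted p = 0.0843). The stress response call was already lost at 0.05 (adjusted p = 0.159) and without the trend with exon length and GC content (adjusted p = 0.0955). By log2 fold change the heat shock and stress response lists gave adjusted p = 0.106 and 0.0702, and the heat shock list gave 0.0731 against matched lists, the stress response list 0.0912 on genes of mean count 100 or more.

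Markers of non-neuronal cells moved in different directions. Astrocyte markers had a median log2 fold change of 0.72, with 7 higher and 1 lower of 29 (adjusted p = 0.0242, 9 and 1 adjusted over the list alone). The adjusted p was 0.152 at a correlation of 0.05 and 0.0523 on genes of mean count 100 or more. In the authors' deposited table Slc1a2, a glial glutamate transporter gene, was at 0.93 (SE 0.24), Glul at 0.72, Id4 at 1.26 and Agt at -3.68 (SE 1.13). Microglia and macrophage markers had a median of -1.88, with 8 lower and none higher of 17, before and after adjustment over the list alone (adjusted p = 0.0091). That call was lost at a correlation of 0.05 (adjusted p = 0.0677) and without the trend with exon length and GC content (adjusted p = 0.0629). Cd68 was at -2.29 (SE 0.40), Csf1r at -3.09 (SE 0.66), Lyz2 at -2.25 (SE 0.71) and Tyrobp at -4.05 (SE 1.34), with mean normalized counts from 9.85 for Tyrobp to 503 for Cd68. The microglia list had a median mean normalized count of 15.5. Only 2 of its members reached 100, 1 above and 1 below 0, too few for a test on genes of that count. Endothelial and mural markers gave 4 lower of 19 (adjusted p = 0.0566, 4 adjusted over the list alone, but 7.33e-04 by log2 fold change, 0.0273 by ranks and 0.0162 against matched lists), namely Cldn5 (-6.24, mean count 3.00), Acta2 (-1.73), Tagln (-1.42) and Pdgfrb (-1.21). Fibroblast and meningeal markers gave 2 higher and 3 lower of 23 (adjusted p = 0.626), with Fbln1 at 1.53, Postn at -1.82, Mgp at -2.16 and Col6a1 at -0.49. Oligodendrocyte markers gave 2 higher and 2 lower of 13 (adjusted p = 0.522), with Mog at 0.99, Cnp at 0.51, Lhfpl3 at -0.76 and Ugt8a at -1.03. Both lists kept their counts when adjusted over the list alone. Radial glia and progenitor markers gave 4 higher and 4 lower of 26 (adjusted p = 0.702, 7 and 7 adjusted over the list alone), with Hes1 (2.17) and Emx1 (1.41) higher and Sox3 (-1.90) and Neurog2 (-1.88) lower.

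**Figure D4:**
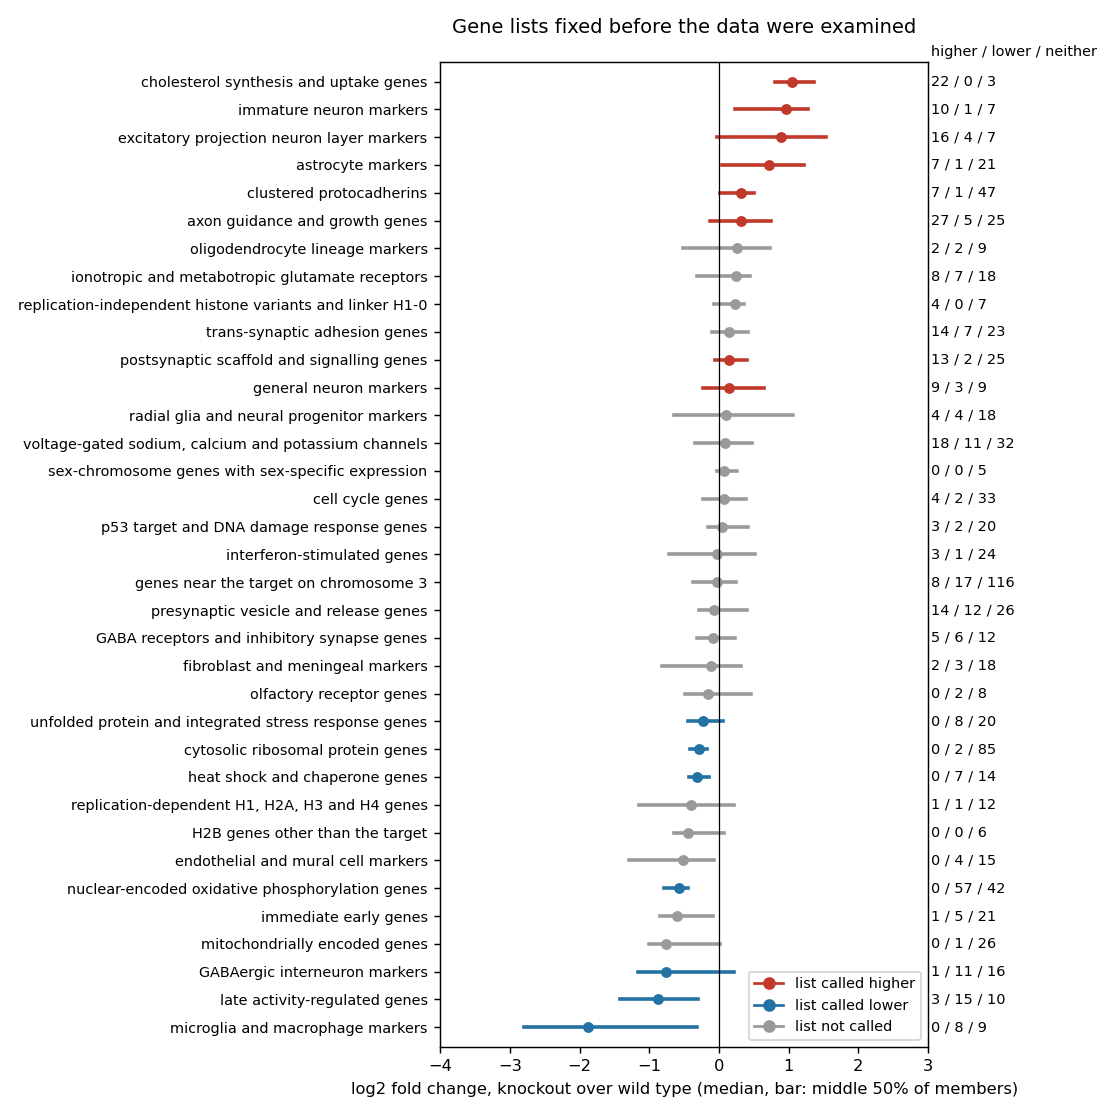
Median log2 fold change, knockout over wild type, of the tested members of each of the 35 gene lists, with bars over the middle 50% of members, computed from the authors' deposited table. Red lists were called higher and blue lists lower by cameraPR, and the numbers at the right count members higher, lower and neither. Cholesterol genes (median 1.04) stand at the top and microglia markers (-1.88), with a median mean normalized count of 15.5, at the bottom.

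The histone gene lists other than the target did not pass cameraPR. Replication-independent variants gave 4 higher of 11 (adjusted p = 0.0863, 4 adjusted over the list alone), with Macroh2a2, a macroH2A gene, at 0.86 (SE 0.13), H1f10 at 0.75, H3f3a at 0.41 and H1f0 at 0.28 in the authors' deposited table. Replication-dependent H1, H2A, H3 and H4 genes gave 1 higher, H2ac25 at 0.58, and 1 lower, H2ac20, of 14, before and after adjustment over the list alone (adjusted p = 0.626). Many of these transcripts lack poly(A) tails, which limits their recovery by this method. The list of 6 other H2B genes gave adjusted p = 0.702 and no calls adjusted over the list alone. Cell cycle genes gave 4 higher and 2 lower of 39 (adjusted p = 0.352), with Rrm2 at 1.73, Mcm7 at 0.59, Cenpe at 0.56 and Kif11 at -0.53. Targets of p53 gave 3 higher and 2 lower of 25 (adjusted p = 0.626), with Sesn1 at 0.65, Trp53inp1 at 0.76, Cdkn1a at -0.50 and Zmat3 at -0.56. Interferon-stimulated genes gave 3 higher, Stat2 (1.49), H2-D1 (0.57) and H2-K1 (1.07), and 1 lower, B2m (-0.99), of 28 (adjusted p = 0.702). Their median (-0.03) and mean (-0.24) lay below 0 while the test pointed up. Of 10 olfactory receptor genes, Or8b53 (-4.60) and Or2t1 (-2.34) fell (adjusted p = 0.519). The counts of these lists did not change when adjusted over the list alone. None of 5 sex-specific genes of the sex chromosomes passed (adjusted p = 0.928, none adjusted over the list alone), with Xist at 0.37 (SE 1.96) and Ddx3y at -0.12 (SE 2.19). All 5 lay between -0.12 and 0.37, so the group means showed no clear imbalance of the sexes between the genotypes. SEs this wide mark a spread between libraries of the same genotype. Without values per library the sex of each stays unknown, so an exact balance is not shown.

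Called genes were more abundant than other tested genes, and the higher and lower genes differed in length. Called genes had a median mean count of 1158 against 272 for the other genes (permutation test across genes, p = 1e-05, the smallest that 100000 resamples can give). The median SE fell from 0.664 under a mean count of 100 to 0.127 at 1000 or more, so abundant genes were called more easily. The difference in mean count can follow from that alone. Higher and lower genes did not differ detectably in mean count, with medians of 1201 and 1100 (permutation p = 0.214). The median exon length was 5328 bases for higher genes, 3876 for lower genes and 3679 for the others. Higher genes were thus longer than lower genes by 1452 bases at the median (permutation p = 1e-05). Median gene lengths were 39692 and 20288 bases (permutation p = 1e-05). Across 14969 tested protein-coding genes, exon length and the Wald statistic of the authors' deposited table were correlated with Spearman's rho of 0.178. In the tenth of shortest genes 57 were higher and 223 lower, and in the tenth of longest genes 276 were higher and 158 lower.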

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

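The choroid plexus marker lists and the final bound of their test were chosen after the genes without a p had been seen.

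In the authors' deposited table, 9 genes carried no p, so no comparison in the report uses them. Of these, 3 had a mean normalized count of at least 50, namely Rpl22l1 (2023), Ttr (1089) and Hspb3 (168). Ttr, the gene of transthyretin and the dominant transcript of choroid plexus epithelium, had a log2 fold change of -11.30 (SE 2.00), and Calml4 (-4.72), Cldn2 (-3.47) and Kcnj13 (-6.57) were among the other genes without a p.

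A candidate explanation for Ttr is choroid plexus tissue in some wild-type libraries. Markers of that tissue whose values had not been looked at did not single it out: 12 tested markers had a median log2 fold change of -0.38 (bootstrap 95% interval -1.11 to 0.71), and their median statistic lay at percentile 16.6 of 10000 lists matched on mean count. As first written, the bound counted any median inside the central 95% of matched lists against this explanation, and that bound was met. It was judged too weak once the value had been seen, because the interval reaches from a clear fall to a rise over 12 markers with a median mean normalized count of 13.3. The 1 of these markers past the threshold was Ace, which rose to 1.09 (SE 0.28) at a mean normalized count of 1264. The full list of 25 tested markers, which includes those seen first, had a median of -1.04 with 3 lower and 1 higher (cameraPR adjusted p = 0.073, within a range over the alternatives from 0.00805 against matched lists and 0.0264 by ranks to 0.955 by log2 fold change and 0.974 on genes of mean count 100 or more), among them Wfdc2 at -8.06 (mean count 10.7) and Slc4a5 at -2.44. That full list had a median mean normalized count of 10.8, and the tests by log2 fold change and on genes of mean count 100 or more left out most of it. Those 2 values therefore say little of the list. Tissue of another kind in a library and an effect of genotype on these genes cannot be told apart here, since no values per library were used.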

How the results depend on the processing

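Alternatives that removed the trend with exon length and GC content or kept protein-coding genes only were chosen after seeing the data. The count of called genes, 3948, was within 1.5 times under 9 of 14 alternatives. It was 2522 at an adjusted p of 0.01 (47.3% lower), 1230 at an absolute log2 fold change of at least 1, 1105 in a test of a log2 fold change over 0.25 (44.0% lower), 74 with an empirical null (31.1% lower) and 1 with a t distribution of 6 degrees of freedom (100% lower). The last follows from its construction, since with 6 degrees of freedom few statistics reach a p that survives adjustment over 18085 genes, and it ignores any sharing of spread between genes. The empirical null follows from a statistic with 1.96 times the normal width, whose cause was not tested. Centring on genes of mean count 100 or more moved fold changes by 0.0149 and the share lower to 46.8%, and the cause was not tested. Of 149 named called genes, 126 lost the call with the empirical null, 148 with the t distribution, 43 in the test over 0.25, 9 without the length and GC trend and 2 without independent filtering. None changed direction. The 15 called lists became 7 at a preset correlation of 0.05 and 4 at 0.1, as a larger correlation widens the null. Those 4 kept their call under every alternative. The other 5 alternatives gave 10 to 18 lists and none reversed a call. The difference in exon length kept its direction and its side of the threshold at 0.01 and 0.1, and H2bc21 stood at -3.44 with centring. No paired analysis was possible because the deposited comparison holds no values per library, so the shared replicate numbers could not be used. For the same reason leaving out a replicate, other normalizations and count models, an estimated correlation and other splits of the libraries were not run. Depth limits genes under a mean count of 100, of which 9.59% were called against 30.6% of genes at 1000 or more.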

Other observations

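Further lists of genes were drawn up after the results above had been seen, and their adjusted p values are over these 14 lists only. Other mitochondrial and metabolic genes fell with those of oxidative phosphorylation. Of 16 tricarboxylic acid cycle genes, 14 fell and none rose (median log2 fold change -0.45, cameraPR adjusted p = 2.17e-08). Mitochondrial ribosomal protein genes gave 28 lower and 1 higher of 80 (median -0.36, adjusted p = 3.42e-09), and vacuolar ATPase subunit genes 10 lower of 21 (median -0.35, adjusted p = 2.89e-06). Glycolysis genes gave 9 lower and 2 higher of 16 (adjusted p = 1.42e-04, but 0.426 when ranked by log2 fold change), with Gapdh at -0.44 and Ldhb at -0.97 but Aldoc, an astrocyte-enriched aldolase gene, at 2.04. Proteasome subunit genes moved less, with 3 lower of 37 and a median of -0.19 (adjusted p = 0.00686). That call was lost at a preset correlation of 0.05 (adjusted p = 0.0733) and of 0.1 (0.189), by log2 fold change (0.147) and without the trend with exon length and GC content (0.0702). Fatty acid synthesis and desaturation genes rose with those of cholesterol synthesis, 10 of 15 (median 0.79, adjusted p = 3.68e-08), with Scd1 at 2.22 (SE 0.32), Fads2 at 1.44 (SE 0.21) and Scd2 at 1.31 (SE 0.18) in the authors' deposited table.

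Neuropeptide and secretory granule genes gave 8 lower and 1 higher of 25 (median -0.58, adjusted p = 0.00291), among them Cck (-2.03), Vgf (-1.72) and Scg2 (-1.28), while Nts rose to 1.87. The call was lost at a correlation of 0.1 (adjusted p = 0.101) and without the trend with exon length and GC content (0.0753). Vgf and Scg2 are also in the late activity-regulated list, and Npy in that of interneuron markers. Striatal neuron markers gave 6 higher and 3 lower of 23 (adjusted p = 0.0296), with Rasgrp2 at 1.63 and Foxp1 at 1.30. That call was lost at correlations of 0.05 and 0.1 (adjusted p = 0.11 and 0.216), on genes of mean count 100 or more (0.101), by log2 fold change (0.181) and without the trend with exon length and GC content (0.0753). Perineuronal net and cartilage-type matrix genes (2 higher and 5 lower of 22, adjusted p = 0.52) and retinoic acid pathway genes (3 higher and 1 lower of 19, adjusted p = 0.194) did not pass with the Wald statistic. Ranked by log2 fold change both did (adjusted p = 5.77e-04 and 0.0232), and the retinoic acid list also on genes of mean count 100 or more (0.0446).

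The pseudogene BC002163 (chromosome 16, 42955631 to 42955949, GRCm38) is 99.4% identical to Ndufs5 over 319 bases, and fell to a log2 fold change of -5.59 while Ndufs5 stood at 1.35 (SE 0.57, adjusted p = 0.074). Rpl15-ps2 (chromosome 9, 72060937 to 72061549) is 98.7% identical to Rpl15 over 613 bases, and Rpl15 stood at 0.07 (SE 0.19). The SE of Xist (1.96) and of the 4 tested Y-linked genes (2.13 to 2.51) lay at or above percentile 99.8 of the 1000 genes nearest in mean count, whose median SE was 0.122 for Xist.

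For the paragraph on energy metabolism and sterol synthesis, the comparison with ribosomal protein genes was chosen after their values were seen, and the matched lists before theirs were. The fall of oxidative phosphorylation genes and the rise of cholesterol genes were set against the trend of the statistic with exon length and GC content. Among 10000 lists matched on exon length, GC content and mean count, the median statistic of 93 oxidative phosphorylation genes lay at percentile 0, with a median log2 fold change of -0.57 against -0.18 (-0.25 to -0.11 over 95% of the matched lists). That of the 25 cholesterol genes lay at percentile 100, with 1.04 against -0.05. Both argue against the trend as the whole cause, though about -0.18 of the fall is shared with matched genes. An equal shift of all short, abundant transcripts is argued against by ribosomal protein genes, whose median lay 0.28 (bootstrap SE 0.05) above that of the list. That comparison took them to be shorter, but their median exon length was 1726 bases against 1569. They also fell, with a median of -0.29, so a shared shift behind part of the fall stays open. An effect of the genotype and a difference in preparation or density of the cultures, for which the labels give no date, may both stand behind these changes.

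For the markers of neuron types, all tests were chosen after seeing the data, and those of other cell types were changed once more because the microglia markers first used, 2.78 below projection neuron and 2.60 below astrocyte markers, have a median mean normalized count of 15.5. A lower share of GABAergic neurons may account for the fall of 10 pan-GABAergic genes, all below 0 and 5 past the threshold. A common log2 fold change of -1.02 was not rejected for these 10 genes (Cochran Q p = 0.883 by a chi-square approximation). Errors shared between genes can raise that p. With SEs of 0.27 to 0.49, values from -0.50 to -1.32 were not told apart, so this test cannot decide for that explanation. A common fold change was rejected for the whole list of 28 genes (Cochran Q p = 7.41e-12 by the same chi-square approximation). There Npy stood at -2.89 and 8 lay above 0, so a lower share of GABAergic neurons does not alone account for that list. As sole cause of the rise of projection neuron markers, it was first set against other cell types. At a mean count of 100 or more, these markers lay 0.68 (bootstrap SE 0.32) above 46 pooled markers of non-neuronal types. That passed the bound of 2 SE first set against it. The bound was tightened afterwards, since those types go both ways and astrocyte markers differed by 0.18 (bootstrap SE 0.34) over both full lists. That comparison therefore does not decide. A lower share of GABAergic neurons alone would raise all 27 projection neuron markers by a common amount. Yet 16 were called higher and 4 lower, with 20 above and 7 below 0, all at a mean count of 100 or more. These values argue against it as sole cause for that list. A common fold change was not tested there, and a part in the rise stays open. For a lower share of all neurons, the test run first, a negative median of general neuron markers, was undecided at 0.14 (bootstrap SE 0.20). Astrocyte markers lay 1.05 (bootstrap SE 0.29) above those of the other non-neuronal types at a mean count of 100 or more. This argues only against a form in which all non-neuronal types gain share alike. Types need not do so, so a lower share of all neurons stays undecided. Neurons at an earlier stage in the knockout cultures are a further hypothesis: the median of 16 early-stage genes outside the marker lists was 0.45 (list adjusted p = 1.42e-04) and that of 18 late-stage genes -0.29 (3.35e-04), a difference of 0.74 (bootstrap SE 0.27), but whether genotype or culture sets the stage was not tested and the direction rests on the sign read from H2bc21.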
